A study of Mus musculus with 8 samples.

How the data were processed

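Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 8 libraries of mouse leukaemia cells from bone marrow. The cells carry the MLL-AF9 fusion and a doxycycline-inducible Klf4 construct (TetO-Klf4), and GFP-positive cells were sorted from leukaemic mice at 0, 6, 12 and 24 hours, with 2 libraries per time. Groups and replicate numbers were taken from the sample labels. The labels do not say whether the libraries of one time came from separate mice. The p-values of agreement and trends therefore measure the spread between these libraries, which may be technical. The p-values of gene lists compare genes with the calls held fixed, and carry no spread between libraries.

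Reads were processed with BWA, SAMtools and MACS2 on the mm10 build, per the submitters' processing notes, and versions and settings are not given in the sources used here. The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled samples. Each peak has a fold enrichment, as deposited by the authors. It is a linear ratio of the pile-up at the summit to the local background, with 1 added to each. The −log10 p-value and −log10 q-value of each peak were also deposited by the authors, and the lowest −log10 q in the lists was 2.00. The integer score and the position of the summit were deposited by the authors in the same lists, and the score was not used for any result. For the named regions these per-peak values served only to describe, rank or filter peaks within a list. They were also summarised per library, as the depth index below and as median folds in shared regions for the closing section; folds of different libraries are not on a common scale, since they depend on depth. Whether reads were shifted for the transposase, and how duplicates or mitochondrial reads were treated, is not stated in the sources used here. Each list held 2 or 3 peaks on the mitochondrial chromosome, so mitochondrial reads were not all removed before peak calling.

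Total read counts were not used here. A depth index was computed in their place: fold enrichment and −log10 p together give the whole-number pile-up and the local background of a peak, within a tolerance of 0.001, for 99.8% to 99.9% of the peaks of each list. The lowest local background of a list, divided by the smallest peak width, gave the background in tags per kb. It was 2.67 and 1.50 at 0h, 2.35 and 2.58 at 6h, 2.63 and 2.23 at 12h, and 2.30 and 2.37 at 24h, for replicates 1 and 2. A shallower library gives fewer and narrower peaks, so the absence of a peak is weakest as evidence in the second 0h library. Intervals on shares of regions are Wilson 95% intervals and cover counting error only.

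Peaks on the 19 autosomes, X and Y were used. Peaks of the 8 libraries that overlapped by at least 1 bp were merged into 32730 regions. A region was called gained at a later time when both libraries of that time and neither 0h library had a peak there, and lost in the reverse case. Counts were set against the same counts under the other 2 ways to split the same 4 libraries into pairs, since 3 splits allow no p-value under 0.05. Regions parting all libraries were counted likewise over the 28 choices of 2 of the 8 libraries and the 35 splits into 4 and 4. The similarity of peak lists was the base-pair Jaccard index, tested one-sided over the 105 divisions of the libraries into pairs. Trends with time were tested two-sided by exact permutation over 2520 arrangements of the times, with Benjamini-Hochberg adjustment over a family of 4 measures.

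Genes came from a table of 21887 protein-coding genes on the same assembly (GRCm38), which gives start and end but no strand or exons. The planned distance to a transcript start was therefore replaced by the distance to the nearer end of any gene. Peaks within 1 kb of a gene end were counted as near, and a region was assigned to the gene with the nearest end within 100 kb of its strongest summit. The planned search for the KLF consensus was not analysed here, because no genome sequence was used. The 15 gene lists, with 321 entries of which 320 matched a symbol, were fixed before the data were examined. Each list was tested two-sided by permuting gene labels, with 10000 random gene sets matched on the number of regions per gene, with Benjamini-Hochberg adjustment over 30 tests.

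Named items followed a rule written before the data were examined. It took Klf4; the 10 gained and 10 lost regions of 24h with the highest mean percentile of fold enrichment; the 5 genes with most gained and most lost regions; up to 4 members per gene list; and 5 gained and 5 lost regions each for 6h and 12h. Some list members that the rule takes are not reported here. Alternatives were peaks with −log10 q of at least 5, lists of equal length (the 14826 strongest peaks by −log10 p of each library), a cover of at least 50%, stricter presence, each library left out in turn, and a block on the replicate number. Calls at equal list length were made within the cut lists. A region gained there can hold a deposited 0h peak below the cut, and likewise for lost regions. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. The scripts were tested on simulated data for 24h against 0h over 32730 regions, where 200 of 200 planted gained regions and 200 of 200 planted lost regions were recovered. Planted regions had no missed calls, so this checks the code and not the power to find changes in real lists. Of simulated gene lists, 0% without enrichment and 100% with enrichment were under 0.05, so the list test was conservative there.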

Results

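The series profiled open chromatin in sorted MLL-AF9 leukaemia cells after induction of Klf4, a zinc-finger transcription factor, to ask how accessibility changed as leukaemic cells were eliminated. The labels do not say whether the 0h cells had received doxycycline, so 0h is used here as the first time point and not as an uninduced state. The 8 libraries fell into 4 time points of 2 libraries each, at 0, 6, 12 and 24 hours. Peak lists held 21763 and 15641 peaks at 0h, 17328 and 18074 at 6h, 21903 and 19728 at 12h, and 15109 and 14826 at 24h on the main chromosomes. Background ran from 1.5 tags per kb in the second 0h library to 2.67 in the first, which makes the 0h pair the most uneven. No 2 lists were identical. Of the 32730 merged regions, 9170 had a peak in all 8 libraries and 9125 in 1 library.

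The Klf4 gene (mm10, chromosome 4, 55527137 to 55532475) had a peak at every time. A peak inside the gene was called in all 8 libraries, with its start between 55530055 and 55530330. Its fold enrichment within each list was 6.42 and 6.88 at 0h, 7.78 and 7.72 at 6h, 6.05 and 7.57 at 12h, and 6.12 and 5.26 at 24h. A second peak, at the higher end of the gene, was called in every library except the second 0h library. The TetO-Klf4 construct shares exons with the gene, so peaks over exons cannot be assigned to one copy.

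Distal sites, farther than 1 kb from a gene end, were fewest at 24h. Distal peaks numbered 10642 ± 3376 at 0h, 9507 ± 401 at 6h, 12206 ± 1367 at 12h and 7210 ± 273 at 24h (SD, n = 2). Peaks near gene ends moved less, from 8061 ± 952 at 0h to 8195 ± 127, 8610 ± 171 and 7758 ± 73 at 6h, 12h and 24h (SD, n = 2). The share of peaks near gene ends was 43.7% ± 5.0 at 0h, 46.3% ± 0.66 at 6h, 41.4% ± 2.2 at 12h and 51.8% ± 1.2 at 24h (SD, n = 2). With lists of equal length the share was 50.0% ± 2.1, 51.4% ± 0.38, 50.7% ± 0.19 and 52.1% ± 0.85 in that order, so the times then differed by less than the spread at 0h.

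Neither measure followed time in order. For the number of peaks, Spearman's rho with hours was -0.39 (exact permutation p = 0.36, adjusted p = 0.72, n = 8) and Pearson's r was -0.45 (exact permutation p = 0.25, adjusted p = 0.51). For the share near gene ends, rho was 0.39 (exact permutation p = 0.36, adjusted p = 0.72, n = 8) and r was 0.61 (exact permutation p = 0.11, adjusted p = 0.46). Without the 24h libraries r turned to 0.38 for the number of peaks and -0.30 for the share, so both directions rest on 24h.

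**Figure D1:**
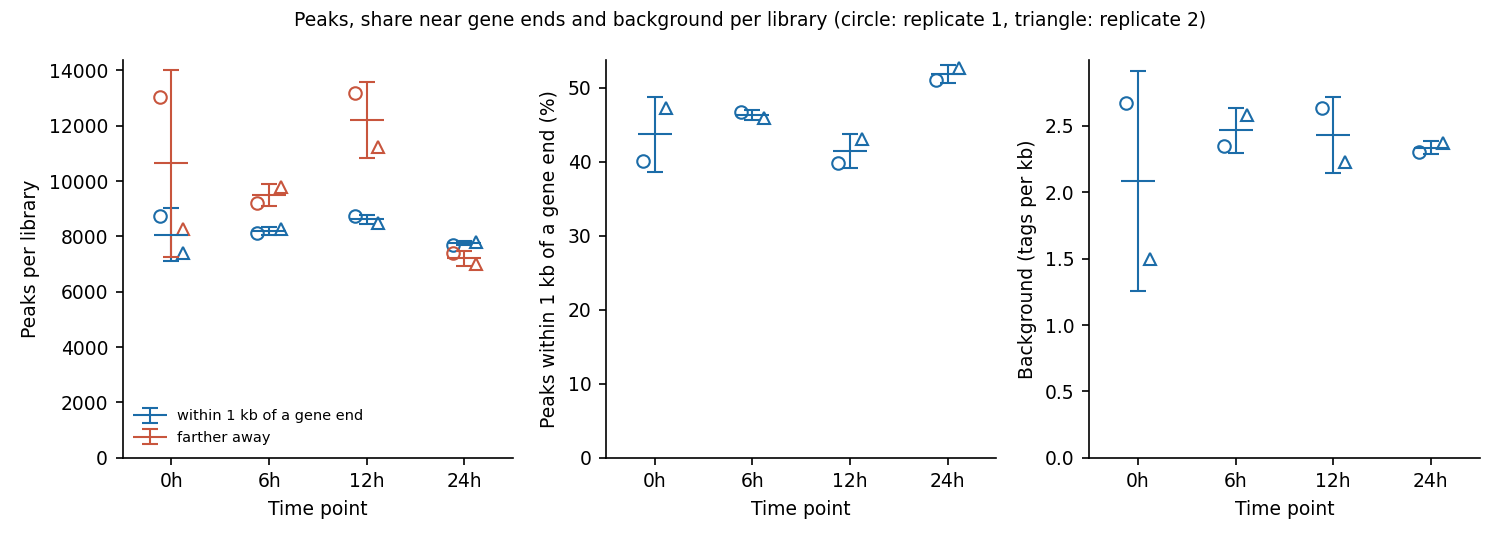
Peaks per library near gene ends and farther away (left), share of peaks within 1 kb of a gene end in percent (middle) and background in tags per kb (right), by time point. Circles are replicate 1, triangles replicate 2, and bars the mean ± SD of 2 libraries; distal peaks are fewest at 24h (7210 ± 273), and the second 0h library has the lowest background (1.5).

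Counted in base pairs, libraries of one time shared little more of their peaks than libraries of different times. The mean Jaccard index was 0.511 over the 4 same-time pairs and 0.497 over the 24 other pairs (one-sided exact permutation p = 0.25, with 0.0095 the smallest possible). The 24h pair was the most alike at 0.565, and the 0h pair the least alike of all pairs at 0.368. Median peak width was 460 and 282 bp in the 0h libraries, and a base-pair index depends on width. Without the first 0h library the difference rose from 0.0142 to 0.0593, and without the second to 0.0449 (exact permutation p = 0.0095 each). It turned to -0.00286 without the first 12h library, and to -0.00235 and -0.00169 without the first and the second 24h library. With fixed windows around summits, chosen after seeing the data, the difference was 0.0183 (one-sided exact permutation p = 0.019).

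At 6h, the gained region with the highest mean percentile of fold enrichment lay 10 bp from an end of Dhx36, a helicase that unwinds G-quadruplexes (chromosome 3, 62506777 to 62507301; fold 13.7 and 12.7). Other leading gained regions lay inside Itgb2, the beta chain of the leukocyte integrins (chromosome 10, 77550953 to 77551274; fold 10.4 in both 6h libraries), inside Ccbe1 and Egln2, and 16.4 kb from Apbb1ip. The Itgb2, Ccbe1 and Egln2 regions were called in all 6 later libraries. Lost regions included an end of Tpd52l1 (fold 11.4 and 9.07 at 0h), a site inside App, which encodes the amyloid precursor protein, a site 2.96 kb from Glipr1l3, a site inside Ppm1h, and a site on chromosome 12 with no gene end within 100 kb. The Tpd52l1, Glipr1l3 and App regions were called again in both 12h libraries.

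In all, 604 regions were gained and 767 lost at 6h, 1371 together, while the other splits of the 4 libraries gave 1325 and 1579. With lists of equal length the counts were 583 and 581, 1164 together against 971 and 1006. The gained count was 2549 and 933 without the first and the second 0h library, and 2410 and 2043 without the first and the second 6h library; the lost count was 2105, 5151, 1507 and 1621 in that order.

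At 12h, leading gained regions lay inside Anp32e, a chaperone of the histone variant H2A.Z (chromosome 3, 95942652 to 95942991; fold 10.1 and 12.7), inside Gm13277, and 34.8 kb from Rsl24d1. Gained sites on chromosomes 4 and 16 had no gene end within 100 kb. The Anp32e region was called in both libraries of 12h and of 24h and in none of 0h or 6h. Lost regions were led by a site inside Clec1a and nearest to an end of Clec12b, genes of C-type lectin receptors (chromosome 6, 129434304 to 129434665; fold 11.3 in both 0h libraries), which was called in both 6h libraries and in none of 12h or 24h. A lost site inside Cds1 was nearest to an end of Gm42134, another lay inside Ppm1h, and lost sites on chromosomes 8 and 12 had no gene end within 100 kb.

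In all, 1319 regions were gained and 475 lost at 12h, 1794 together against 1655 and 1229 under the other splits. Gained regions made up 73.5% as deposited but 53.8% at equal list length, where 661 were gained and 568 lost, 1229 together against 861 and 892. The gained count was 4171 and 1893 without the first and the second 0h library, and 3163 and 4249 without the first and the second 12h library; the lost count was 1575, 3972, 1179 and 855 in that order.

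At 24h, regions gained against 0h lay at Dhx36 (fold 11.9 and 11.0), inside Itgb2 (fold 11.1 and 8.96) and Ccbe1, and 19 bp from an end of Cbx2, a Polycomb protein (chromosome 11, 119022843 to 119023418; fold 8.41 and 11.6). The leading gained region lay 8.56 kb from Btbd16 (chromosome 7, 130834421 to 130834599; fold 11.1 and 12.7). Others lay inside Tcf20 and Slc36a3 and at some distance from Myo16, from Rspo2, an agonist of Wnt signalling, and from Dynlt1b. Of these 10 regions, those at Slc36a3, Ccbe1, Myo16, Itgb2, Cbx2 and Dynlt1b were called in all 6 later libraries. The Rspo2 region was called at 12h and 24h and in no library of 0h or 6h.

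Regions lost at 24h included one inside Bsn, which encodes a presynaptic scaffold protein (chromosome 9, 108120671 to 108121035; fold 12.98 and 11.2 at 0h), and one 81.5 kb from Rgs1, a regulator of G-protein signalling (chromosome 1, 144330410 to 144330873; fold 11.0 and 10.8). Those at Bsn, Rgs1, Gxylt1, Tafa4 and Trdmt1, a tRNA methyltransferase, and one on chromosome 11 with no gene end within 100 kb, were called in all 6 libraries of 0h, 6h and 12h and in none of 24h. Sites at ends of Zfp169 (19 bp) and Ddx47 (44 bp) and the site inside Clec1a were also lost. The strongest lost region, 39.2 kb from Mex3c on chromosome 18, had a fold of 37.9 and 45.5 at 0h. It had a peak in both libraries of 6h and in 1 of the 2 libraries of 12h. The other lost regions named for 24h had folds of at most 13.1 at 0h. Peaks in artefact-prone sequence were not filtered out here. All 10 gained and all 10 lost regions named for 24h were also found at equal list length. This was likely beforehand, since they were chosen for high fold enrichment and cutting lists adds no peaks.

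In all, 367 regions were gained and 1451 lost at 24h, 1818 together against 1139 and 1073 under the other splits. Gained regions made up 20.2% as deposited but 49.2% at equal list length, where 718 were gained and 741 lost, 1459 together against 860 and 869. Equal lengths draw the gained and lost counts together. The first 0h list was cut from 21763 to 14826 peaks, so regions among the 718 can hold a deposited 0h peak below the cut. The gained count was 1750 and 594 without the first and the second 0h library, and 1306 and 1386 without the first and the second 24h library; the lost count was 3089, 6877, 2363 and 2305 in that order.

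**Figure D2:**
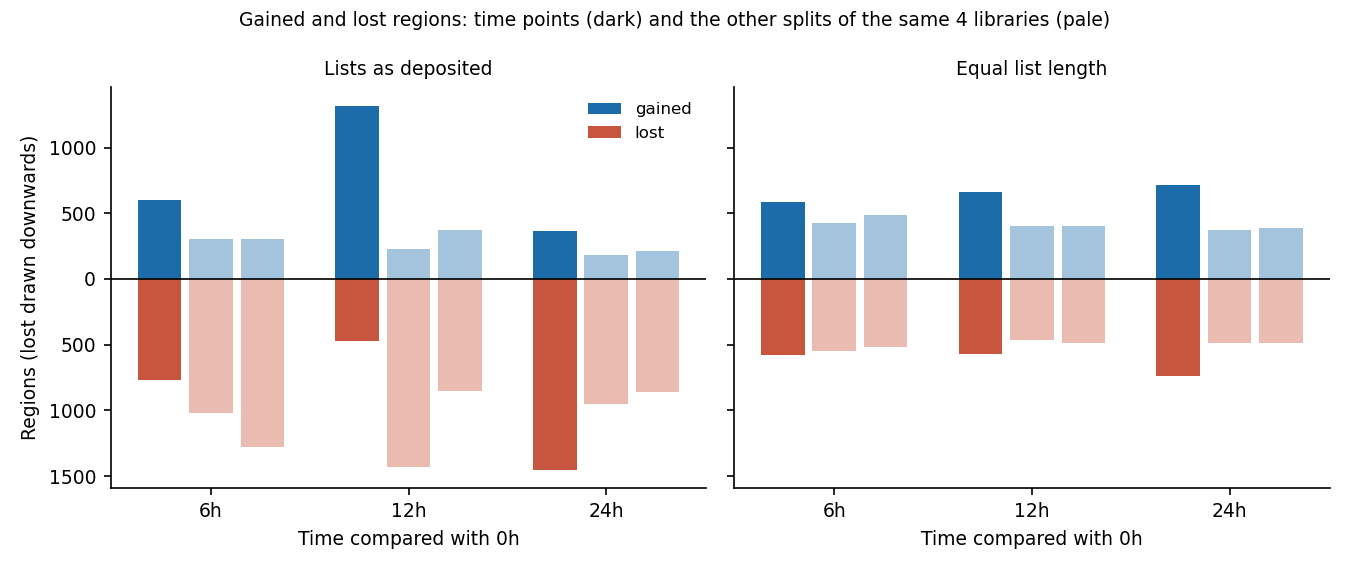
Regions gained (upwards) and lost (downwards) against 0h at 6h, 12h and 24h, for lists as deposited (left) and lists of equal length (right). Dark bars are the time points and pale bars the other splits of the same 4 libraries; at 24h the deposited lists give 367 gained and 1451 lost regions, and lists of equal length 718 and 741.

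Gained regions at 24h lay near gene ends more often than lost regions. The share was 20.2% (95% interval 16.4% to 24.6%) of the gained and 12.7% (11.1% to 14.5%) of the lost regions. With lists of equal length it was 28.1% (24.97% to 31.5%) and 14.3% (12.0% to 17.0%). In the other splits of the 4 libraries, which side counts as gained is arbitrary. Their shares were 10.8% against 21.0% and 12.2% against 27.1% as deposited. The gap was 7.48 percentage points for the time points and -10.2 and -14.9 for these splits. At equal list length it was 13.8, and -10.5 and -17.9 for these splits. In size, the gap at 24h was thus below that of at least 1 other split in both settings. Against the first 0h library alone the shares at 24h were 19.9% and 12.8%, and against the second alone 38.0% and 10.1%. At 6h the shares were 17.9% (15.0% to 21.1%) of the gained and 12.1% (10.0% to 14.6%) of the lost regions, and 20.8% against 14.3% at equal list length. At 12h they were 14.6% against 12.2%, and 18.6% against 17.4% at equal list length. The intervals cover counting error only.

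Several genes had more than 1 changed region at 24h. Bcl11a, a transcriptional repressor of blood lineages, the receptor gene Notch3, Ckap4, Cfap46 and 9230019H11Rik had 2 gained regions each. Atp8b4, Golga5, Jazf1, Nebl and Tbc1d8 had 3 lost regions each, and 9230019H11Rik had 1 lost region besides its gained ones. With lists of equal length the lost regions numbered 3 at Atp8b4, 2 at Golga5 and Nebl, 1 at Tbc1d8 and 0 at Jazf1, and Bcl11a had 1 gained region.

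Among the genes of the MLL-AF9 self-renewal programme, Meis1, a cofactor of Hoxa9, and the kinase gene Cdk6 had 2 lost regions each at 24h. Flt3, Cd34, Hoxa10, Runx2 and Lmo2 had at least 1 lost region, and Hoxa9 and Mecom had a gained region. Of the 24 genes of this list with a region, 7 had a lost region, with 5.41 in matched random sets (permutation of gene labels, p = 0.55, adjusted p = 1). With lists of equal length Meis1 had 1 gained and 1 lost region, and Cdk6 had 1 gained and 0 lost. Of the 7 genes with a lost region 3 still had one there, Flt3, Hoxa10 and Runx2 not among them. The genes with a gained region went from 2 to 6 there, Hoxa9 and Mecom among them. Regions gained only at equal list length can hold a deposited 0h peak below the cut.

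Monocyte and macrophage genes with a lost region included Adgre1, Ccr2 and Cd36, while Irf8, a transcription factor of monocyte development, had a gained region, among 31 genes with a region. With lists of equal length Adgre1 and Ccr2 had 0 lost regions, while Cd36 and Irf8 had theirs. Mmp8, the neutrophil collagenase, was the 1 granulocyte gene of 19 with a gained region. Of 28 apoptosis genes, Pmaip1, which encodes the pro-apoptotic protein Noxa, had a gained region, and those with lost ones included Bcl2l11 and Tnfsf10, the latter with 0 at equal list length. Of 28 cell cycle genes, the inhibitor gene Cdkn1a had a gained region, and Cdkn2a, Ccnd2, Ccne1 and Cdk6 had lost ones, of which only Cdkn2a had one at equal list length. Of 20 inflammatory and NF-kB genes, Socs3 had a gained region, and Nfkb1, Nfkbia, Tnfaip3 and Ccl3 had lost ones, with 0 for Nfkb1 and Nfkbia at equal list length. The 19 genes of the KLF and SP family had 0 gained and 0 lost regions, although Klf7 had 1 gained region at equal list length. Fosl1 was the 1 immediate early gene of 20 with a lost region, but it had 1 gained and 0 lost at equal list length. There the genes of this list with a gained region went from 0 to 4. These gains, and that of Klf7, can hold a deposited 0h peak below the cut. Cxcl10 was the 1 interferon response gene of 15 with a lost region. Esrrb and Epcam had lost regions among 11 pluripotency and epithelial genes, with 0 for Epcam at equal list length.

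Of 41 markers of other cell types with a region, 8 had a gained or lost region at 24h, 4 of them among the 8 megakaryocyte genes. Nfe2 and Plek of the megakaryocyte list had gained regions, and Vwf and Fli1 lost ones, with 0 for Fli1 at equal list length. Pax5 of the B lineage, Lef1 of the T and NK lineage and Pdgfrb of stroma had a lost region, Pecam1 of endothelium a gained one, and the 5 erythroid genes with a region had 0 of either kind. B lineage genes with a peak in the gene or within 10 kb numbered 10 and 9 at 0h, 10 and 10 at 6h, 11 and 11 at 12h, and 6 and 7 at 24h, of 16 genes. Stromal and endothelial genes with such a peak numbered 9 and 3 at 0h, 6 and 5 at 6h, 7 and 6 at 12h, and 1 and 3 at 24h, of 16 genes. Megakaryocyte genes with one numbered 11 and 9 at 0h, 9 and 9 at 6h, 10 and 9 at 12h, and 8 and 9 at 24h, of 16 genes. For the erythroid list the numbers were 6 and 3, 5 and 5, 4 and 4, and 4 and 5, of 16 genes, and for the T and NK list 10 and 7, 9 and 6, 9 and 8, and 6 and 7, of 18 genes. Monocyte and macrophage genes with one numbered 28 and 19 at 0h and 20 and 18 at 24h, of 32 genes, and the 24h lists were the shortest.

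By permutation of gene labels among genes with as many regions, 0 of 30 tests passed at 24h (smallest p = 0.11, for megakaryocyte genes among gained regions, adjusted p = 1), and 0 were under 0.05 before adjustment. At 12h 0 of 30 passed the permutation test (smallest p = 0.081, adjusted p = 1), with 0 under 0.05 before adjustment. At 6h 0 of 30 passed the permutation test, with 1 under 0.05 before adjustment, the granulocyte genes among gained regions (3 genes against 0.533 in matched random sets, p = 0.029, adjusted p = 0.76). Without the second 0h library, 1 list passed at 24h: 8 of 11 pluripotency and epithelial genes had a lost region, against 2.83 in matched random sets (permutation test, adjusted p = 0.036). Under the same setting 8 of 10 stromal and endothelial genes, markers of other cells, had a lost region against 4.12 in matched random sets. Without the first 0h library, 12 of 24 genes of the self-renewal programme had a gained region against 6.45. Without the first 24h library, 4 of 8 megakaryocyte genes had a gained region against 1.12. These settings leave 1 library at 0h or at 24h.

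Some regions separated 0h from every later library. The regions at Itgb2, Ccbe1, Slc36a3, Egln2, Dynlt1b, Cbx2 and Mmp8 were among 88 called in all 6 later libraries and neither 0h library, of which 39 were also found at equal list length. A further 200 regions were called in both 0h libraries and no later one, of which 57 were also found at equal list length. The total of 288 was reached by 5 of the 28 choices of 2 libraries, the real one included, with 543 as the highest other. At equal list length the total was 261, and it was reached by 1 of 28, with 209 as the highest other.

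Fewer regions separated 0h and 6h from 12h and 24h. There were 45 called in all 4 late libraries only and 40 in all 4 early libraries only. The total of 85 was reached by 6 of 35 splits, with 160 as the highest other. At equal list length the total was 84, reached by 1 of 35, with 66 as the highest other.

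**Figure D3:**
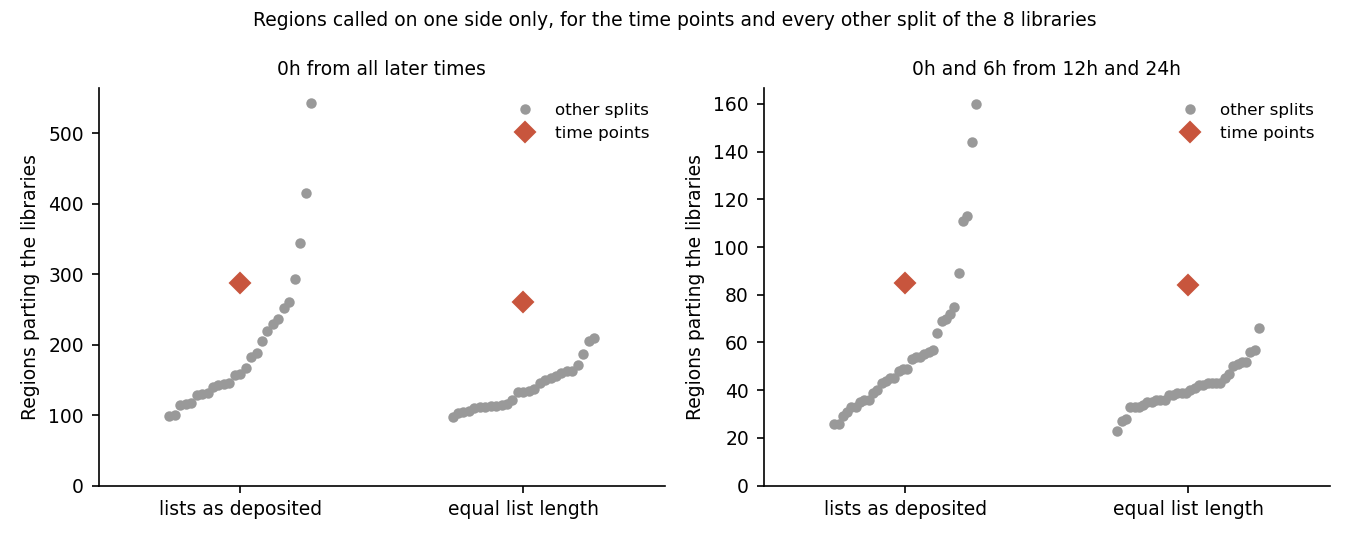
Number of regions called on one side only when 2 libraries are parted from the other 6 (left) and 4 from 4 (right), for lists as deposited and of equal length. Diamonds are the splits by time and grey points every other split; the time split is above all others only at equal list length (261 against 209, and 84 against 66).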

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

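Outside the main chromosomes, 18 sequences carried a peak in at least 1 library. On 1 unplaced sequence each of the 6 later libraries had at least 1 peak and the 2 0h libraries had 0, in data that no comparison used. These are peak calls and not measured levels, and absence in the shallow second 0h library is weak evidence. No explanation was tested.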

How the results depend on the processing

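The fixed windows around summits, the trends over times up to 12h only and the gene lists at −log10 q of at least 5 were chosen after seeing the data; the other alternatives were set before the data were examined. The 2 trends with time mirror each other in rank in the deposited lists, so they count as 1 result there. They kept their direction, with p above 0.05, under each alternative run except over times up to 12h only. There rho turned to 0.48 for the number of peaks and -0.48 for the share near gene ends (exact permutation p = 0.40 each, n = 6). The cause was not tested. With each library left out rho ran from -0.59 to -0.092 for the number of peaks and from 0.092 to 0.59 for the share near gene ends. Replicate agreement stayed above 0.05 with −log10 q of at least 5, equal list length and 50% reciprocal overlap, but passed with fixed windows (difference 0.0183, exact permutation p = 0.019); it ran from -0.00286 to 0.0593 with each library left out, and the cause was not tested. Equal list length moved the counts of 12h gained (661), 24h gained (718) and 24h lost regions (741), by its construction, since it evens out the list lengths. At −log10 q of at least 5 the lost regions of 12h fell to 312. Requiring −log10 q of at least 5 for presence but not for absence lowered counts by construction, to 311 gained and 358 lost at 6h, 811 and 217 at 12h, 209 and 762 at 24h, 124 regions parting 0h from later times, and 32 parting early from late. With each library left out, which asks for agreement of fewer libraries, counts ran from 603 to 2549 (6h gained), 765 to 5151 (6h lost), 1318 to 4249 (12h gained), 474 to 3972 (12h lost), 366 to 1750 (24h gained), 1447 to 6877 (24h lost), 343 to 3046 (0h from later) and 143 to 210 (early from late). The number of gene lists passing at 24h stayed at 0 except without the second 0h library (range 0 to 1; adjusted p 0.036 to 1). Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated from -0.013 to 0.005. With the replicate block, rho was -0.44 for the number of peaks and 0.44 for the share near gene ends, same-numbered pairs differed from other pairs by 0.00031, and the counts were identical by construction (604, 767, 1319, 475, 367 and 1451), so the block changed no call. The lost regions of named list genes at 24h often ended at equal list length, where 3 of 7 genes of the self-renewal programme still had one. The KLF motif alternatives were not run, as no genome sequence was used. The low depth of the second 0h library limits every statement that a region was absent at 0h.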

Other observations

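Between later times, the step from 12h to 24h had the most lost regions as deposited. There, 119 regions were gained and 2231 lost, against totals of 883 and 831 under the other splits of those libraries. At equal list length 497 were gained and 621 lost. Of all regions, 232 were called in the 6 libraries of 0h, 6h and 12h and missed by both 24h libraries, and 84 at equal list length. The pair of 0h replicate 2 and 24h replicate 2 gave as many, 232 and 91, so the count does not set 24h apart. The regions missed at 24h were led by sites assigned to Rgs1 (81458 bp from a gene end), Tmem231 (14 bp), Tafa4 (44067 bp), Rab38 (6235 bp) and Castor2 (18 bp). These were named after their values were seen. At 12h 404 regions were called in both libraries and at no other time, but 99 at equal list length.

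The counts over other splits of the libraries were planned before the data were examined, but what would decide between explanations was written for all tests below only after their values had been seen.

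The 24h lists were short. Lower depth, as the index measures it, is argued against. Log2 peak number was fitted on log2 background through the other 6 libraries. From that line the 24h libraries lay at -0.33 and -0.38, and the lowest of the others at -0.15. The line leans on the shallow second 0h library. The index also does not show where tags fell. The strongest peak, on chromosome 2, had a −log10 p of 9906 and 10357.5 at 24h and at most 9681 elsewhere. Lower depth in the rest of the genome thus cannot be told apart. Weaker enrichment cannot be told apart: in the 9170 regions called in all 8 libraries the higher 24h library had a median fold of 10.4148 against 10.3973 in the lowest library of 6h or 12h, and the other 24h library had 10.0984, on folds that also depend on depth. A loss of distal accessibility at 24h, the biological reading given by the time points, may also account for it and stays open.

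Regions parting the times were weighed against chance. As deposited, chance cannot be excluded: 5 of 28 choices gave at least the 288 regions that part 0h from later times (highest other 543), and 6 of 35 splits gave at least the 85 that part early from late (highest other 160). The highest splits set 0h replicate 1 and 12h replicate 1, the longest lists, apart from the rest, alone or with 6h replicate 2 and 12h replicate 2. At equal list length, 1 of 28 (261 against 209) and 1 of 35 (84 against 66) reached the real totals, the smallest shares these splits allow. Choices of 2 that held the shallow second 0h library tended to give high totals there, 146 to 206 besides the real one. Only 7 choices hold it, too few for a share under 0.05, so the 28 choices cannot exclude chance. For early against late, the highest other split at equal list length (66, 0h with 12h) also kept both libraries of each time together. The remaining split of that kind, 0h with 24h, gave 51. Splits of that kind are too few for a share under 0.05, so the 35 splits cannot exclude chance either. A candidate explanation is a small set of sites that changed with time; it was found and tested on the same data, and other differences between times were not tested.

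Gained regions at 24h lay near gene ends more often than lost ones, but the gap was smaller in size than in another split of the same libraries. The shallow second 0h library cannot be told apart as the cause: against the first 0h library alone, the gap between gained and lost regions was 7.02 percentage points as deposited and 12.5 at equal list length, and against the second 0h library alone 27.9 and 29.5. Between 24h and 12h it was 9.49 and 14.1, where the other splits reached 10.5 and 5.9. Between 24h and 6h it was 1.04 and 7.29, below another split of those libraries (11.0 and 9.92). Weaker enrichment at distal sites cannot be told apart, because the ratio of median fold near gene ends to that elsewhere was 1.21 and 1.26 in the 24h libraries and reached 1.23 in another library, and a redistribution of accessibility towards gene ends may also account for the pattern.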
